A study of Caenorhabditis elegans with 2 samples.

How the data were processed

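The samples were chromatin immunoprecipitation sequencing (ChIP-seq) libraries from whole Caenorhabditis elegans young adults of mixed sex. Per the labels, the worms carried T26A5.8 fused at its C-terminus to a green fluorescent protein and FLAG tag, and chromatin was sheared by sonication and recovered with an antibody against the fluorescent protein. The strain had a mutated unc-119 gene and an integrated transgene. Worms were collected 63 h after synchronization from starved first-stage larvae. The labels give 1 group of 2 biological replicates, numbered 3 and 4. No condition was compared with another, and the labels name no paired or batched samples. Control libraries were not analysed here.

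The analysis used region lists that the authors deposited, and reads were not analysed here. Per the labels and the deposited notes, each replicate has a list of peaks and background regions that served as input to the irreproducible discovery rate (IDR) procedure, which keeps regions ranked alike in replicates. A further such list was made from the pooled alignments of both replicates, with a control alignment, and an optimal IDR-thresholded list was made from the replicate lists and the pooled list. All lists were deposited on builds ce11 and ce10. The aligner, the peak caller and their versions are not given in the sources used here. Each region in the deposited lists carries a signal, the enrichment value of the authors' caller, whose scaling is not stated, so that it was used only to describe and rank regions within a list. Each region also carries a −log10 q-value as the authors' caller gave it, and the position of its summit. The deposited −log10 q-value ran from 1.93 to 2.40 in the thresholded list and was at the highest value for 126 of its 369 regions, so it was not used for ranking. No signal value in the thresholded list was identical to one in the pooled list, and 361 of the 369 thresholded regions overlapped a pooled entry. Read depth is unknown because the lists give no counts. The binomial intervals below therefore cover the counting of regions or genes, not of reads.

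Coordinates are on ce11 and count from 1. Chromosome names and lengths of the ce11 lists were compared with the reference genome WBcel235, and all regions ended within its chromosomes. Genes came from Ensembl release 115, with 46890 genes on the 6 nuclear chromosomes. Protein-coding genes took their Ensembl names and other genes the RefSeq name of the same gene identifier, available for 46881 genes, and 3 heat shock names were not found. This matching was settled after list counts under other matchings had been seen, and its effect is given with the other alternatives. No coordinates were carried between builds, and the ce10 lists were used only for counts, for agreement within that build and for comparing signal values.

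The promoter window ran from 1000 bp upstream to 200 bp downstream of a gene start, and a region was placed by its summit. Summits were assigned in order to promoter, exon, intron, gene end (within 500 bp downstream) or intergenic sequence. Thresholded regions were compared with the 29559 pooled candidate regions that did not overlap them, by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family. Gene lists and gene classes were tested over genes whose promoter window held the summit of any pooled candidate region. The 19 gene lists were ribosomal proteins, translation factors, proteasome, oxidative phosphorylation, splicing factors, histones, major sperm proteins, vitellogenins, collagens, nuclear hormone receptors, homeobox genes, heat shock and stress, germline, intestine, muscle, pharynx, neurons, hypodermis and spliced leader RNA. Members were limited to protein-coding genes, or to snRNA genes for the spliced leader list. Replicate signals were compared across regions by Pearson's r of log10 values and Spearman's rho, with 100000 permutations (1000 for all pooled entries), 2-sided like the other permutation tests. Sharing with the strongest entries of a replicate required 50% reciprocal overlap. Presence of each 6-mer within 50 bp of the summit was compared with presence in a window of the same length 400 bp away by an exact binomial test on discordant regions, and the same test was run on 20 random draws of 369 other candidate regions. Intervals are exact 95% binomial intervals. Regions and neighbouring genes are not independent replicates, so p-values describe these lists and not a population of worms.

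The genes named in the text were those whose promoter window held the summit of 1 of the 25 thresholded regions of highest signal, T26A5.8 and unc-119, and up to 4 members by signal of each fixed list with a region. Regions with no gene in the window were named by position and nearest gene start. Names outside this rule are marked as chosen after their values were seen. The lists, windows, tests and alternative settings were fixed before the data were examined. These settings were the upper part of the list by signal (184 regions), other promoter windows, other overlap rules, the weaker 15000 candidate regions as background, protein-coding genes only, all annotated genes as background, other 6-mer windows, other windows at the transgene loci, the ce10 lists, and each replicate left out. To leave out a replicate, the 369 strongest entries of the other replicate's own list took the place of the thresholded regions. The distance of 200 bp to tRNA, snoRNA and snRNA genes, the gene-end window from 200 bp upstream to 500 bp downstream, the circular shifts of regions along each chromosome, the subsets of regions used for 6-mers, and the tests of repeated sequence were chosen after the data had been seen. Regions away from small RNA genes were those with no tRNA, snoRNA or snRNA gene within 200 bp of the summit. Regions at other small RNA genes, such as rpr-1, were not removed.

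The tests were checked on simulated data. With 10 members of the ribosomal protein list planted among random regions, the list was called in 100% of 20 simulations, and other lists in 0.556% of tests. Annotation classes with no effect were called in 2% of tests. A planted 6-mer was called in 100% of 5 simulations. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.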

Results

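ChIP-seq of tagged T26A5.8 in young adult worms was available as 1 group of 2 biological replicates, 3 and 4. The series asks where in the genome this protein is found. The authors' thresholded list held 369 regions on ce11 and covered 0.129 Mb, with a median width of 360 bp. Each replicate list and the pooled list held 30000 candidate regions, including background. Signal values are the authors' own, and read depth is unknown.

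The strongest regions lay at genes for small non-coding RNAs. Of the 25 regions of highest signal, 10 had their summit within 200 bp of a snoRNA gene, 3 of a tRNA gene and 2 of an snRNA gene, a distance chosen after the data had been seen. The first was at chromosome V, 8500425 to 8500695, in the gene body of pxn-1, with its summit 26 bp upstream of the snoRNA gene ZK994.7 and a signal of 393.9 (230.3 in replicate 3 and 172.5 in replicate 4). The tRNA-Lys gene ZK994.t2 also had this summit in its promoter window. The next, at chromosome V, 12303517 to 12303754, lay in the body of frm-7 over the snoRNA genes C51F7.3 and C51F7.4, with a signal of 354.8 (185.6 and 153.1). The region at chromosome I, 13463845 to 13464060, had its summit 18 bp inside rpr-1, which encodes the RNA of ribonuclease P, the enzyme that trims the 5′ end of tRNA precursors. Its signal was 333.2 (210.8 and 127.1). All 25 were above the median of the 369 regions in both replicates.

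Further snoRNA genes among these 25 regions were W03C9.9, with a signal of 277.3 at chromosome II, 11960695 to 11960919, T03F7.8, with 272.1 at chromosome V, 11314124 to 11314306, Y23H5B.10, ZK265.10, Y75B12B.12, Y43F8C.22, C41C4.11 and T06C12.16. The tRNA genes were M02F4.t1 (glycine) and M02F4.t2 (glutamate), which face away from each other on chromosome X, F15G9.t1 and F15G9.t2 (both alanine), and C04A11.t1 (leucine). The snRNA genes were W05B2.8 and sls-2.4, whose product is a spliced leader RNA added to messages in trans. Several of these summits also fell in windows of protein-coding genes: egg-5, sre-23, Y75B12B.11, mrps-28, chst-1 and C41C4.9. They also fell in windows of the pseudogene Y23H5B.7 and of the unclassified non-coding genes R12E2.18, T03F7.14, Y23H5B.13, M02F4.12, F15G9.8, F15G9.9 and C41C4.15.

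Away from small RNA genes, the strongest region with a protein-coding gene in its window lay at chromosome III, 3867460 to 3867630, in intergenic sequence 313 bp upstream of the ribosomal protein gene rpl-3, with a signal of 246.0 (138.1 in replicate 3 and 98.1 in replicate 4). The region at chromosome III, 13464655 to 13464779, had its summit 75 bp upstream of kel-3 and inside a 3′ UTR of cdk-5, with a signal of 221.2. The non-coding gene K02F3.13 had a summit at -981 bp from its start, in the body of dos-3. Y65B4BR.10 and wwp-1 shared a region at chromosome I, 536729 to 537088. F42A6.6 had a summit 78 bp inside its start, at chromosome IV, 3336615 to 3336974. The summits at rpl-3 and kel-3 also lay 443 and 93 bp past the ends of acs-19 and ant-1.1. Those at K02F3.13, wwp-1 and F42A6.6 lay 261, 322 and 125 bp past the ends of zip-2, icd-2 and hrpa-1. These neighbours were named after the values were seen, and the regions cannot be assigned to a gene start alone. Another 4 of the 25 regions had no gene in the promoter window. They lay at chromosome II, 5661644 to 5661962, in an intron of mdt-26, at chromosome II, 8441631 to 8441742, in an intron of lips-10 with eif-3.G as the nearest gene start, at chromosome IV, 17281274 to 17281519, between the 3′ ends of hsp-1 and nra-1 with the snoRNA gene F26D10.24 as the nearest start, and at chromosome III, 1419915 to 1420023, in an exon of lelo-2 with Y82E9BR.3 as the nearest start.

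Genes for tRNAs, snoRNAs and snRNAs held regions in their promoter windows more often than other genes did. Of 529 tRNA genes with any candidate region in the window, 149 (28.2%, 95% interval 24.4 to 32.2) had a thresholded region, against 3.57% of other genes (odds ratio 10.6, adjusted p = 4.5e-78, Fisher's exact test). The share was 48 of 224 snoRNA genes (21.4%, odds ratio 6.03, adjusted p = 5.2e-19, Fisher's exact test) and 12 of 60 snRNA genes (20%, odds ratio 5.22, adjusted p = 3.7e-05, Fisher's exact test). Against a group that held these classes, protein-coding genes were lower, at 161 of 6548 (2.46%, odds ratio 0.323, adjusted p = 3.1e-35, Fisher's exact test), as were pseudogenes, at 6 of 481 (adjusted p = 9.7e-05, Fisher's exact test), and piRNA genes, at 26 of 888 (adjusted p = 0.015, Fisher's exact test). The values for miRNA genes (3 of 102), rRNA genes (0 of 2) and unclassified ncRNA genes (154 of 3139) did not pass the test. The snRNA call was lost with the window from 500 bp upstream to 100 bp downstream (8.82%, adjusted p = 0.385, Fisher's exact test), and the piRNA call with the window from 2000 bp upstream to 500 bp downstream (3.81% against 4.26%, adjusted p = 0.525, Fisher's exact test).

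By position, 116 of the 369 regions (31.4%, 95% interval 26.7 to 36.4) had their summit within 200 bp of a tRNA gene, against 1.22% of the 29559 other candidate regions (odds ratio 37.1, p = 1.1e-118, Fisher's exact test). Another 45 (12.2%, against 0.447%) lay beside snoRNA genes and 12 (3.25%, against 0.203%) beside snRNA genes. Together 173 regions (46.9%) lay beside these genes. When the regions were moved along each chromosome 1000 times, the mean number beside tRNA genes was 1.04 and the highest was 5. The median summit lay 8 bp inside the start of tRNA genes, with quartiles at -23.25 and 40.25 bp, and at -33 bp from the start of snoRNA genes (the plot of summit positions). At snRNA genes the median lay 160.5 bp downstream of the start, beyond the median gene length of 110 bp, and 9 of the 12 summits lay past the gene.

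**Figure D1:**
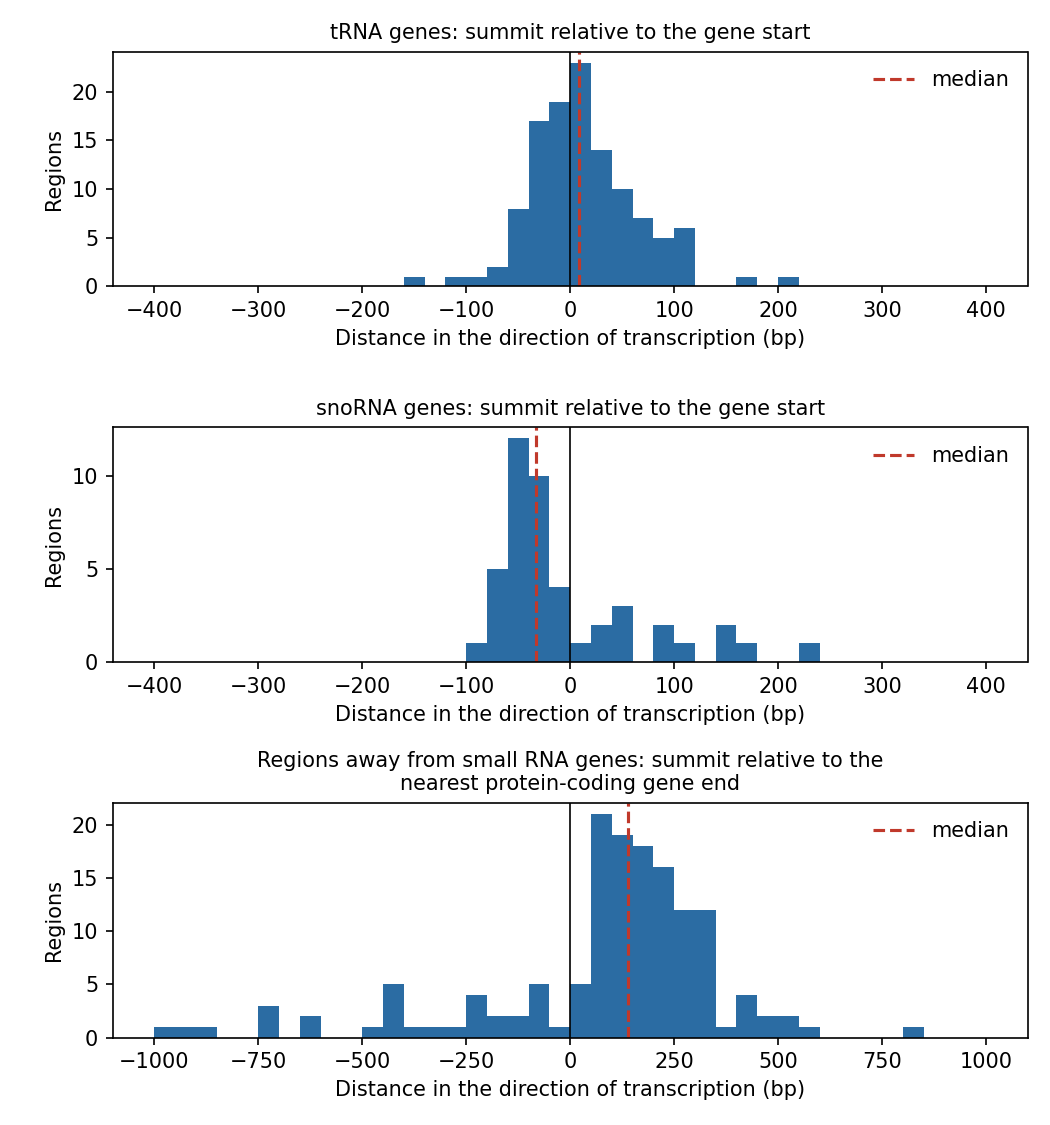
Histograms of summit position in bp along the direction of transcription, with the number of thresholded regions on the vertical axis, for 116 regions beside tRNA genes, 45 beside snoRNA genes (both relative to the gene start) and 145 other regions within 1000 bp of a protein-coding gene end. Dashed lines mark the medians at 8, -33 and 138 bp, and solid lines mark the gene start or end.

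Summits fell at promoters in 284 of 369 regions (77.0%, 95% interval 72.3 to 81.2), against 34.4% of the other candidate regions (odds ratio 6.36, adjusted p = 6.1e-61, Fisher's exact test). Exons held 38 summits (10.3% against 34.4%), introns 18 (4.88% against 20.5%) and intergenic sequence 7 (1.90% against 7.28%), all lower than among other candidates (adjusted p = 5.7e-26, 4.2e-17 and 8.0e-06, Fisher's exact test). The classes exclude each other and promoters were assigned first, so a higher promoter share lowers the other shares. These tests therefore do not show separate depletions. After promoters, exons and introns were assigned, gene ends held 22 summits (adjusted p = 0.0134, Fisher's exact test). This was 5.96% of all 369 regions, against 3.41% of all other candidates. The call ended in the 184 strongest regions (5.43%, adjusted p = 0.151, Fisher's exact test). The order leaves few summits for this class, so these shares do not measure how many regions lay near gene ends. Without that order, 157 of the 369 summits (42.5%) lay from 200 bp upstream to 500 bp downstream of a protein-coding gene end, a window chosen after the data had been seen. The promoter windows of 561 genes held a summit, among them 149 tRNA, 48 snoRNA and 161 protein-coding genes. In 47 of these protein-coding genes the strongest summit lay within 200 bp of a small RNA gene. With protein-coding genes only, the promoter share was 35.5% against 23.05% (p = 7.7e-08, Fisher's exact test). The 196 regions away from small RNA genes leave out only those beside tRNA, snoRNA and snRNA genes, so the region at rpr-1 is among them. Of these 196 regions, 91 (46.4%) lay at promoters of protein-coding genes, against 23.03% of other candidates (odds ratio 2.90, p = 8.1e-13, Fisher's exact test).

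**Figure D2:**
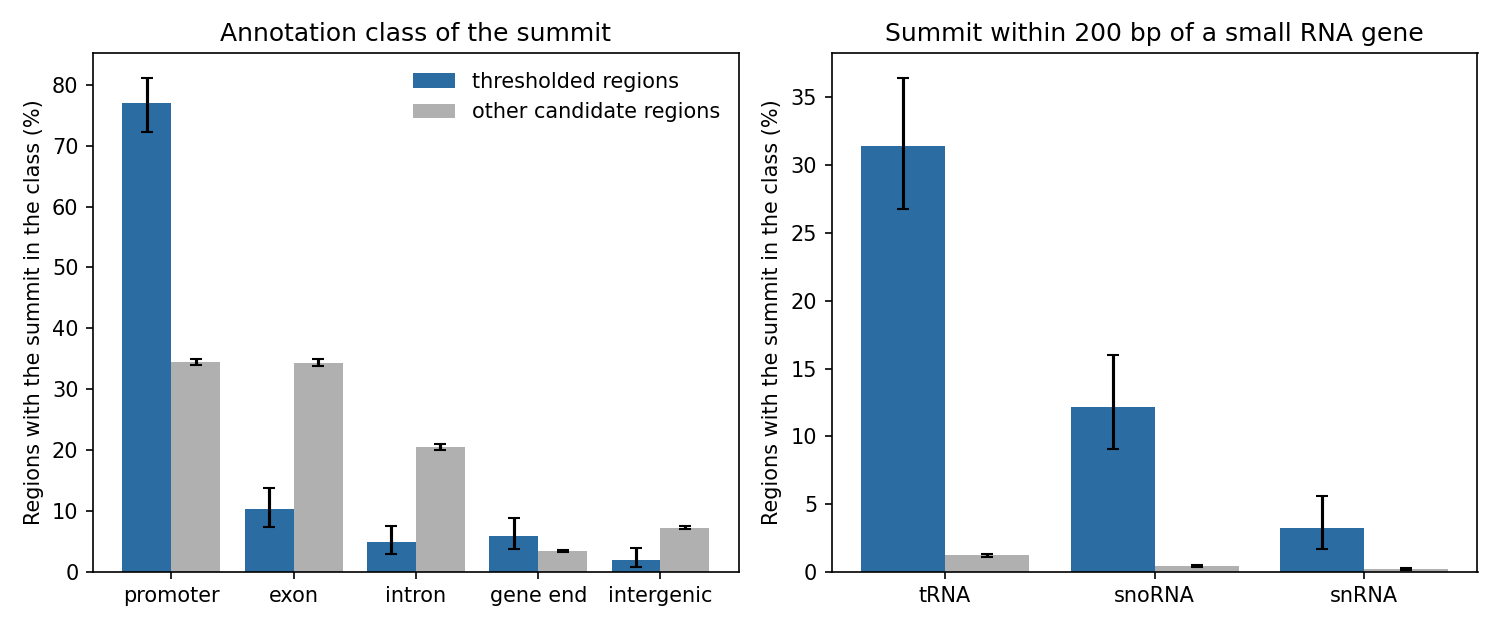
Share of region summits in percent by annotation class (left) and within 200 bp of a tRNA, snoRNA or snRNA gene (right), for 369 thresholded regions and 29559 other candidate regions, with exact 95% binomial intervals as error bars. Promoters held 77.0% of thresholded summits and 34.4% of others, and the neighbourhood of tRNA genes held 31.4% and 1.22%.

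Among the 19 lists, ribosomal protein genes and spliced leader RNA genes held regions in their promoter windows more often than other genes of their kind. For ribosomal proteins, 9 of 55 genes had a region (16.36%, against 2.34% of other protein-coding genes, odds ratio 8.16, adjusted p = 1.2e-04, Fisher's exact test). The strongest were rpl-3, rpl-35 (signal 147.8), rps-16 (135.2) and rps-26 (128.1), and none of the 9 had its strongest summit within 200 bp of a small RNA gene. The summits at rpl-3, rps-16 and rps-26 also lay 443, 164 and 176 bp past the ends of acs-19, fib-1 and dnj-12, neighbours named after the values were seen, so these regions cannot be assigned to a gene start alone. For spliced leader RNA, 7 of 13 genes had a region (53.8%, against 10.6% of other snRNA genes, odds ratio 9.80, adjusted p = 0.0195, Fisher's exact test), led by sls-2.4 (244.6), sls-2.1 (137.5) and the neighbours sls-2.14 and sls-2.15 (both 129.2, from the same region). This call was lost in the 184 strongest regions (30.8% against 6.38%), with the narrower window (16.7% against 7.14%) and against all annotated snRNA genes (23.3% against 5.05%), with adjusted p = 0.214, 1 and 0.0617 by Fisher's exact test. The strongest summits at sls-2.4 and sls-2.15 lay 110 and 175 bp downstream of the start, outside the narrower window, which ends at 100 bp. A promoter window thus reaches past such short genes, and these summits are not upstream of them. Other snRNA genes had a region in 5 of 47 cases.

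No other list passed. The chaperone genes hsp-60 and hsp-1 were the 2 of 11 heat shock and stress genes with a region (p = 0.0286, adjusted p = 0.181, Fisher's exact test), with signals of 123.1 and 89.1. The respiratory chain genes cox-6A and cox-5A were 2 of 18 oxidative phosphorylation genes (adjusted p = 0.338, Fisher's exact test), a list that passed with the window from 2000 bp upstream to 500 bp downstream (15.6%, adjusted p = 0.00811, Fisher's exact test). The histone genes his-67 and his-68 shared a region and were 2 of 26. The translation factor list had 1 of 26, eif-2Bgamma, and the nuclear hormone receptors 1 of 67, nhr-255. The summits at cox-6A and eif-2Bgamma lay within 200 bp of an snRNA gene and that at nhr-255 within 200 bp of a tRNA gene, and away from small RNA genes only cox-5A remained of the 18. In this promoter window no region was found for proteasome (0 of 14), splicing factor (0 of 19), major sperm protein (0 of 4), vitellogenin (0 of 2), collagen (0 of 42), homeobox (0 of 20), germline (0 of 21), intestine (0 of 9), muscle (0 of 15), pharynx (0 of 3), neuron (0 of 12) or hypodermis (0 of 10) genes. For collagens the upper limit of the 95% interval was 8.41%, and it was higher for the other lists without a region. In the gene-end window, proteasome, collagen, germline and muscle genes did have regions.

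Chromosome V held fewer thresholded regions than other candidate regions did, with 44 (11.9% against 21.5%, odds ratio 0.495, adjusted p = 1.6e-05, Fisher's exact test). Chromosomes III and IV held 70 each (18.97%, against 14.4% and 14.2%, both adjusted p = 0.0339, Fisher's exact test). Chromosomes I (50), II (60) and X (75) did not pass the test. On X, 67 of the 75 regions lay beside tRNA genes, and X carried 276 of the 612 annotated tRNA genes. Among the 196 regions away from small RNA genes, a subset chosen after the data had been seen, X held 3.57% against 19.6% of other candidates (adjusted p = 4.5e-10, Fisher's exact test). The calls for III and IV were lost in the 184 strongest regions and without replicate 3, and that for III also without replicate 4. In the 196 regions away from small RNA genes both were larger, at 26.5% against 14.5% for III and 23.5% against 14.3% for IV (adjusted p = 3.0e-05 and 9.8e-04, Fisher's exact test).

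Sequence at the summits was richer in G and C than sequence nearby, at 47.1% ± 8.08 (SD over 369 regions) against 35.6% ± 8.71 in the flanks. In other candidate regions the values were 42.8% ± 8.23 and 36.0% ± 8.78. Of the 6-mers tested, 156 were more frequent at summits and 100 less frequent, while random draws of other candidate regions gave a median of 15.5 and a highest count of 35. ACCACT was present in 68 summit windows and 9 flanks (adjusted p = 9.2e-11, exact binomial test), and CGAACC in 56 and 8 (adjusted p = 9.1e-08, exact binomial test). AAAATT was present in 64 and 163 (adjusted p = 1.5e-11, exact binomial test). Regions beside similar gene copies were counted as separate in this test. In the 116 regions beside tRNA genes 89 6-mers passed, and in the 57 beside snoRNA or snRNA genes 1. Fewer regions give less power, so these counts are not comparable. In the 253 regions away from tRNA genes 79 passed, 46 more frequent at summits and 33 less frequent. Of the former, GCGCAC had the lowest p, with 25 summit windows and 2 flanks (adjusted p = 6.4e-04, exact binomial test). No annotated tRNA gene lay within 200 bp of these summits, so its sequence does not account for such 6-mers. Whether T26A5.8 binds them was not tested. Beside tRNA genes, a motif bound by T26A5.8 and sequence that tRNA genes share cannot be told apart. In the 196 regions away from small RNA genes, 2 6-mers passed, both less frequent at summits, with 162 at an unadjusted p under 0.05. With 100 bp on each side 2 passed as well, both more frequent.

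At the tagged gene T26A5.8 (chromosome III, 6462216 to 6462856, reverse strand), 1 thresholded summit lay within 20 kb of the gene start, a count reached around 2709 of 19973 protein-coding genes. This region, at chromosome III, 6464252 to 6464611, had a signal of 139.3 (73.2 in replicate 3 and 54.5 in replicate 4) and lay over the non-coding gene T26A5.10. Without replicate 3 the count was 2, reached around 308 genes. Around unc-119 (chromosome III, 10902641 to 10908935, forward strand), the gene mutated in the strain, no thresholded summit lay within 20 kb.

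The snoRNA regions that led the list were also at the top of both replicates. Over the 369 regions, r between replicates was 0.471 on log10 values and rho was 0.378. Without the 2 regions farthest from the median in replicate 3, r was 0.434. The regions had been selected for similar ranks in these same replicates, so these values, and the overlap of these regions with each replicate's strongest entries, do not test agreement between them. Over the 13229 pooled entries found in both replicates, a set chosen after the data had been seen, r was 0.485 and rho 0.319 (both p = 0.001, the smallest that 1000 permutations can give). Entries are not independent replicates. The pooled list was made from these same replicates and was limited here to entries found in both, so these values are no independent test of agreement either. Of the 369 regions, 281 (76.2%, 95% interval 71.5 to 80.4) overlapped 1 of the 369 strongest entries of replicate 3 and 246 (66.7%, 61.6 to 71.5) 1 of those of replicate 4. Both applied to 188 regions, and neither to 30. Without that selection, the 369 strongest entries of the 2 replicates overlapped each other in 196 of 369 cases.

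**Figure D3:**
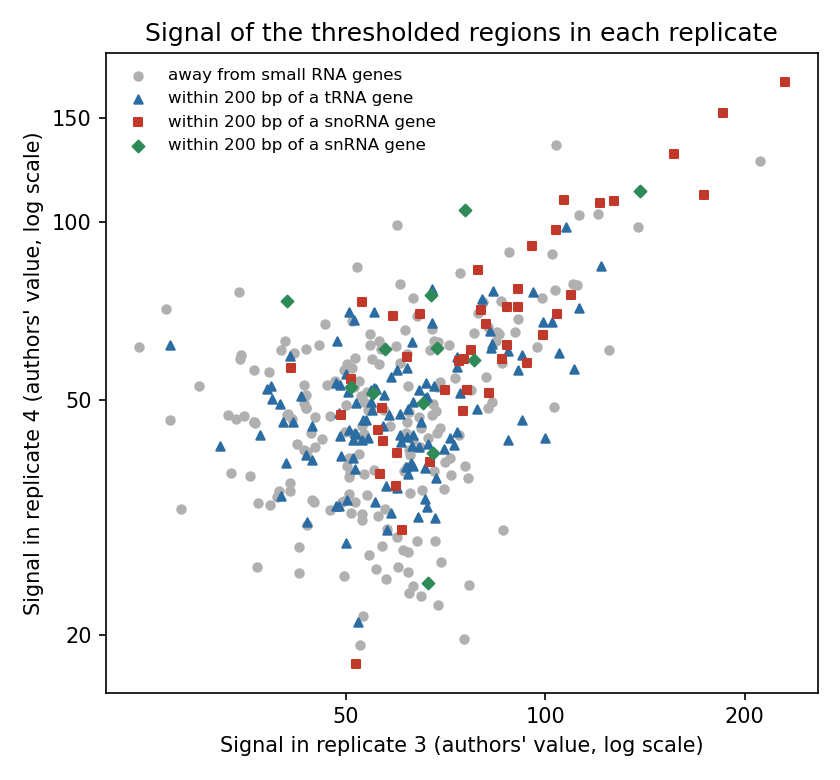
Authors' signal of each of the 369 thresholded regions in replicate 3 (horizontal) and replicate 4 (vertical), both on log axes, 1 point per region, marked by the kind of small RNA gene within 200 bp of the summit. The region at ZK994.7 is the highest point in both, at 230.3 and 172.5.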

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

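The tests on repeated 31-mers in the whole set were chosen before their results were seen. The tests on regions with no repeated 31-mer, on lists of strongly transcribed genes, on the tagged locus and on the builds were chosen after the results had been seen, in whole or in part. The 3 results below were picked out because they are signals in data that the comparisons above do not use or use only as background. The design names no second group, so no biological explanation was tested for any of them.

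Beyond the 135 tRNA genes with a thresholded summit within 200 bp, 363 further tRNA genes had only a candidate region that was not thresholded, so that 498 of the 612 annotated tRNA genes had some region. Reads shared between near-identical copies are a candidate explanation for regions at tRNA, snoRNA and snRNA genes. The median share of 31-mers that recur elsewhere in the genome was 15.1% in thresholded regions beside these genes and 15.7% in other candidates beside them, a difference of -0.60 points (p = 0.44, permutation test). Both sets lie beside the same gene classes, so this comparison cannot show why regions concentrate at these classes. The median was 0% in the 196 thresholded regions away from these genes and in a sample of 2000 other candidates away from them. A median no higher than in other candidates had been set beforehand as evidence against this explanation, but the explanation is kept open for the set because the test did not tell the difference from 0; a first run on means gave -1.72 points (p = 0.082, permutation test). In 42 of the 173 regions no 31-mer around the summit was repeated, so sharing between exact copies of that length does not apply there. Copies that differ by a few bases were not examined and the aligner is not known, so the explanation is not excluded for these regions. The share without a repeated 31-mer was 24.3%, against 24.5% in other candidates beside these genes. Recovery of strongly transcribed genes of any kind may also contribute. It was examined with 5 lists: ribosomal proteins, translation factors, oxidative phosphorylation, vitellogenins and muscle. Of these, 1 (ribosomal proteins) was enriched at the gene start or end. Oxidative phosphorylation also passed at gene ends away from small RNA genes, with start windows left in or out. It passed as well with the window from 2000 bp upstream to 500 bp downstream of the start (adjusted p = 0.00811, Fisher's exact test). Only 2 vitellogenin genes at starts and 3 at ends could be tested. Heat shock and stress and germline genes, not among the 5 lists, passed at gene ends (4 of 13 and 6 of 34, both adjusted p = 0.00566, Fisher's exact test). Neither a control library nor transcript levels were analysed here, so such recovery and binding by T26A5.8 cannot be told apart.

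The ce10 list held 609 thresholded regions, 240 more than the 369 on ce11. Of the 369 ce11 regions, 362 were found on ce10 by their signal, and 362 were among its 369 strongest. The lowest signal was 87.7 on ce11 and 73.9 on ce10, so the ce10 list mostly added weaker regions. Sequence differences between the builds are argued against as the cause, by a criterion rewritten after the values were seen (a first bound of 99% had left them open): of the 1000 strongest ce11 entries, 98.5% of the pooled list and 98.4% of replicate 4's list had an entry of the same signal, within 0.01%, on the same chromosome of ce10. For replicate 3 this share was 6.2% (95% interval 4.79 to 7.88), and the median region width in its list was 364 bp on ce10 and 356 bp on ce11. A different fragment-length setting for replicate 3 may therefore lie behind the difference in number. Why the widths differ was not tested.

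The pooled list held 22 candidate entries within 20 kb of T26A5.8, against a median of 12 and an upper limit of the central 95% of protein-coding genes of 24. Extra copies of the tagged locus in the strain could raise this count. Replicate 3 had 22 entries, under its limit of 23, and replicate 4 had 29, above 23. Missing the limit in any list had first been set as evidence against extra copies, and this was loosened after the counts were seen to lying at or below the median. All 3 counts were above the median and only 1 above its limit, so extra copies and ordinary variation between loci cannot be told apart. The pooled list had 1 entry around unc-119.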

How the results depend on the processing

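Alternatives beyond the planned ones (regions away from small RNA genes, gene-end windows, gene names, 8-mers, regions beside given RNA genes) were chosen after the data had been seen. Of 90 alternative values of the main results, 67 kept their direction and side of the threshold or stayed within their limits, and 23 moved. Of 343 values for single classes, lists and chromosomes, 321 did so, 13 lost their call and 5 gained one. A further 4 gained a call in the other direction from a main value that had not passed. Of these 321, 144 had no region in either setting and 13 others repeated the main values, so the count says little about stability. The cause was not tested unless fewer regions or another unit of counting explain it. The number of regions was 609 on ce10. Sharing with the strongest entries of replicate 3 was 70.1% in the 184 strongest regions, 69.95% on ce10 and 89.97% with 738 entries, and for replicate 4 it was 81.6% with 738 entries. In the 184 strongest regions, 1 chromosome and 1 list passed, 298 genes had a promoter region and 117 6-mers passed. Without a replicate, 1 to 2 chromosomes passed, and T26A5.8 had 1 to 2 summits. For lists, 1 passed with the 500 bp window, against all annotated genes and away from small RNA genes, and 4 passed in the gene-end window with all regions or with those away from small RNA genes. The germline list, with 0 of 21 genes and no call at promoters, passed there with 17.6% of genes in both settings. Outside start windows as well it passed with 21.4%. X, which had no call in the main setting, was called lower away from small RNA genes, at 3.57%. For 6-mers, 98 passed with 25 bp and 79 away from tRNA genes. Away from all small RNA genes, 2 passed with 50 bp (both lower at summits), 2 with 100 bp (both higher) and 0 of the 8-mers (55 unadjusted, exact binomial test). In the 116 regions beside tRNA genes 89 passed, and in the 57 beside snoRNA or snRNA genes 1. With RefSeq names for all genes, 7 of 47 ribosomal protein genes had a region (adjusted p = 0.00249, Fisher's exact test), and Ensembl names for all genes gave 9 of 55. With members of any biotype against all genes, ribosomal proteins (adjusted p = 0.00843) and spliced leader genes (adjusted p = 2.2e-05) passed Fisher's exact test. Read depth is unknown, so weak regions that were not thresholded cannot be called absent. No paired analysis was possible because there is 1 group.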

Other observations

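The tests on snoRNA genes inside and outside protein-coding genes and on tRNA amino acids were chosen before their results were seen. The tests on gene ends and on summit positions were chosen after the results had been seen.

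Regions away from tRNA, snoRNA and snRNA genes often lay near the end of a protein-coding gene, although few genes had such a region. Regions at other small RNA genes, such as rpr-1, were not removed from this set. Of these 196 regions, 124 (63.3%, 95% interval 56.1 to 70.02) had their summit from 200 bp upstream to 500 bp downstream of a protein-coding gene end, against 17.3% of other candidates (odds ratio 8.22, p = 7.6e-46, Fisher's exact test). Among the 83 such regions within the 184 strongest, the shares were 59.04% and 17.6% (p = 4.2e-17, Fisher's exact test). In that window, ribosomal protein genes had a region in 15 of 71 cases (21.1% against 2.62%, adjusted p = 1.5e-08, Fisher's exact test), among them rpl-4 (signal 153.9), rpl-3 (140.9) and rps-6 (124.0). Heat shock and stress genes had 4 of 13 (hsp-1, hsp-110, hsp-60 and hsp-6), germline genes 6 of 34 (prg-1, csr-1, cbd-1, cgh-1, car-1 and pgl-3) and oxidative phosphorylation genes 4 of 28 (atp-1, cox-5B, atp-2 and cox-4). Their adjusted p-values were 0.00227, 0.00227 and 0.0349 by Fisher's exact test. With regions beside small RNA genes included, the value for oxidative phosphorylation was 0.0640 (Fisher's exact test), which does not pass. Of the 124 regions, 51 also lay in a start window, so a region near a gene end is not assigned to that gene alone. With regions and candidates in start windows left out, a test added later, the lists of ribosomal proteins (7 of 45), germline (6 of 28) and oxidative phosphorylation (3 of 15) passed, with adjusted p-values of 9.2e-04, 9.0e-04 and 0.03215, and heat shock and stress (2 of 9) did not, at 0.0858 (Fisher's exact test). The summit past hsp-1 lay 55 bp beyond its end, with a signal of 197.2. These genes were named after their values were seen.

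Among small RNA genes outside the main classes, the RNase P RNA gene rpr-1 and the RNase MRP RNA gene mrpr-1 (signal 123.7, chosen after its value was seen) each had a region, and the 1 Y RNA gene had only a candidate region that was not thresholded. Of 19 spliced leader 2 RNA genes, 7 had a thresholded summit within 200 bp, and of 12 spliced leader 1 RNA genes none had any candidate region. Of 20 rRNA genes, 2 had any candidate region. Whether reads could be placed at single copies of these genes was not tested. The spliced leader 1 and 2 genes therefore cannot be said to differ in binding.

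One hypothesis is that gene ends hold regions where no gene start lies nearby. Nearby was set by a start window narrower than the promoter window. Summits from 500 to 1000 bp upstream of a start were thus kept, though they count as promoter summits above. With regions in a start window (500 bp upstream to 200 bp downstream) left out, 73 of 122 regions (59.8%) still lay at gene ends, against 14.8% of other candidates (odds ratio 8.57, p = 7.4e-30, Fisher's exact test). This is consistent with the hypothesis, which was formed on the same regions. Regions at gene starts outside end windows were also more frequent than among other candidates, at 23 of 72 (31.9% against 12.3%, p = 1.1e-05, Fisher's exact test).

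Another hypothesis is that summits lie further upstream at snoRNA genes than at tRNA genes. The medians were -33 and 8 bp, a difference of -41 bp (p = 0.00069, permutation test), and the summit was upstream of the gene start in 71.1% of 45 snoRNA regions and 42.2% of 116 tRNA regions. The tRNA summits thus may sit nearer the internal promoter that tRNA genes are known to have, which these data do not test.

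A further hypothesis, that snoRNA genes outside protein-coding genes are favoured, stays open: 20 of 130 such genes (15.4%) and 25 of 216 inside protein-coding genes (11.6%) had a region (odds ratio 1.39, p = 0.325, Fisher's exact test). For tRNA genes, no amino acid passed the test against the others, with a smallest adjusted p of 0.647 over 21 amino acids by Fisher's exact test. Alanine was highest among those with over 10 genes, at 13 of 34 genes (38.2% against 21.1%, unadjusted p = 0.0308, Fisher's exact test). A lack of calls had been set beforehand as evidence against a difference, but a p that misses the threshold sets no bound on one, and the odds ratio of alanine was 2.31, so a difference stays open.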
